A study of Homo sapiens with 9 samples.

How the data were processed

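Poly-A selected RNA of N/TERT keratinocytes was sequenced by a commercial provider as paired-end reads of 150 bases from fragmented, randomly primed cDNA, per the labels' protocols. The 9 libraries were grouped by the genotype and title in the labels into control, SGPL1 knockout (KO) and SGPL1 overexpression (OE), 3 each. Each deposited file held whole-number counts of reads per gene that the authors made with featureCounts of the Subread package, version 1.5.2 per the file headers, against Ensembl release 101 on GRCh38. The submitters' processing notes name FastQC, HISAT2 1.03, featureCounts 0.1.0 and DESeq2, so they and the headers give different versions of featureCounts. The counting command in the headers sets no option for read pairs, strand, multi-mapping reads or overlapping genes. Mates of a fragment may therefore be counted separately, and antisense or overlapping genes cannot be told apart. Reads of near-identical gene copies are uncertain. Counts were not normalized before deposit.

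Each file listed 60671 genes, of which 42020 had a symbol and 25939 had a count in at least 1 library. Columns of other series numbered 0. Coordinates are those of the count files, as the lowest start and highest end of a gene's exons, 1-based. Gene types (58453 genes) and GC content (13341 of the 13390 tested genes, 99.6%) came from GENCODE release 29 on the same build, matched by gene identifier, and exon length from the count files.

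Counts were analysed with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1, DESeq2 1.42.0 and version 1.17.8 of data.table). Genes were kept by filterByExpr with a minimum count of 10, which left 13390 genes, and libraries were scaled by TMM. All 9 libraries entered a quasi-likelihood fit with the group as the only term, so that groups shared an estimate of the spread (common biological coefficient of variation 10.2%), and contrasts were tested two-sided. Benjamini-Hochberg adjusted p values under 0.05 counted as changed. CPM were scaled by TMM, and log2 CPM for correlations and principal components used a prior count of 2. Replicate pairs differed by more than sampling noise, with a chi-square per degree of freedom from 2.74 to 11.7, and no 2 libraries were identical. With 3 counts as the floor, limits for genes without reads were taken over the group, and counting intervals of ratios are 95% exact intervals. Reads are not independent molecules, so they cover counting error at most.

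Before the data were examined, the design, the alternatives, 32 gene lists (998 entries found in the files) and the rule for named genes were fixed. The rule took SGPL1, the 8 protein-coding genes with the largest rise and the 8 with the largest fall in each comparison among changed genes with a mean of at least 5 CPM in the higher group and no overlap between the libraries, 24 genes of S1P metabolism, differentiation and calcium whatever their result, and up to 4 members of each list by smallest p. The lists covered sphingolipid metabolism, S1P receptors and S1P export, phosphoethanolamine and PE or PC synthesis, calcium stores and calcium channels, S100 calcium binding proteins, cornified envelope and terminal differentiation, epidermal barrier lipid and inherited ichthyosis genes, basal keratinocyte and hemidesmosome, wound and stress keratinocyte genes, desmosome, adherens and tight junction, cholesterol synthesis, fatty acid synthesis and elongation, cell cycle, p53 targets, unfolded protein response, interferon stimulated genes, inflammatory cytokines and NF-kB targets, YAP and TEAD targets, epithelial mesenchymal transition and matrix, lysosome, Notch pathway and targets, NRF2 targets, hypoxia and glycolysis, MHC class I and antigen presentation, EGFR, MAPK and immediate early genes, fibroblast markers, melanocyte markers, simple epithelial and non-keratinocyte keratins, blood, endothelial and immune markers, mitochondrially encoded mRNA, replication dependent histones and cytosolic ribosomal proteins. They were tested with camera at its preset inter-gene correlation of 0.01, which compares a list with all other genes, if at least 3 members were measured, and the p values were adjusted over the lists of a comparison. The tests were repeated with a correlation estimated from residuals and with fry, which asks whether a list's genes move on balance in a direction, and beside them the changed members were counted over all genes and adjusted over the list alone.

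Because fold changes in KO libraries followed exon length and GC content, an alternative was added after seeing the data. In each library a loess surface (span 0.3) of log2 CPM relative to the mean of all libraries over log2 exon length and GC content was entered as an offset in the same fit. The other alternatives were DESeq2's size factors, DESeq2's Wald test, limma-voom, other filters, fits of only the groups compared, stricter thresholds, the number in the titles as a block, and each library left out in turn. On data simulated from the means and library sizes with about 200 changed genes in each edited group (398 between KO and OE), the fit recovered 55.2%, 61.2% and 93.9% of 1.5-, 2- and 4-fold changes in KO against control, 59.7%, 84.6% and 97.0% in OE against control and 59.7%, 78.8% and 95.5% in KO against OE. Of its calls 6.67%, 7.56% and 6.06% were false (13032 genes). With the KO length trend added to the simulation, 1430 genes and 6 lists without a seeded change were called in KO against control, and 7 genes and 0 lists once the trend was removed (13076 genes).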

Results

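The data were polyadenylated RNA sequencing counts from N/TERT cells, a line of human epidermal keratinocytes immortalised with telomerase. The cells belonged to 3 groups of 3 libraries each: unedited control cells, cells with a CRISPR knockout of SGPL1 (KO) and cells that overexpressed SGPL1 (OE). SGPL1 encodes sphingosine-1-phosphate lyase, the enzyme of the endoplasmic reticulum that irreversibly breaks down sphingosine-1-phosphate (S1P) to phosphoethanolamine and a fatty aldehyde. The series concerns the scaling skin disorder that accompanies loss of this enzyme, with sphingolipids and calcium as its themes. Gene counts summed to 8989198, 9251703 and 8730711 in the control libraries, 8768406, 9410555 and 6317564 in the KO libraries and 8773822, 9566149 and 13330479 in the OE libraries. Between 17280 and 18988 genes had a count in a library, and 3 counts in a library corresponded to 0.225 to 0.475 counts per 1e6 counts (CPM). The submitters call the libraries of a group biological replicates, but the number of edited clones behind them is not given in the sources used here. The p-values therefore measure the spread between these libraries. Principal component 1 held 56.8% of the variance and separated the KO libraries from all others. Correlations of log2 CPM lay between 0.978 and 0.985 within groups and between 0.916 and 0.974 across groups. Values with ± are the mean CPM ± SD (n = 3) or the log2 fold change ± SE, and adjusted p values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 13390 genes.

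SGPL1 itself (ENSG00000166224; GRCh38 chromosome 10, 70815948 to 70881184, plus strand) was counted over all its exons. It had 83.9, 95.1 and 98.3 CPM in the control libraries, 58.8, 58.3 and 61.6 CPM in the KO libraries and 1132, 1104 and 929 CPM in the OE libraries. KO cells thus had 59.6 ± 1.75 CPM against 92.5 ± 7.55 in control cells, 1.55-fold lower, with a log2 fold change of -0.64 ± 0.09 (adjusted p = 5.14e-06). OE cells had 1055 ± 110.1 CPM, 11.4-fold more than the controls (3.51 ± 0.09, adjusted p = 4.90e-18). Between KO and OE cells the difference was 17.7-fold (-4.15 ± 0.10, adjusted p = 3.16e-19). All 3 KO libraries lay below and all 3 OE libraries above every control library. Gene counts cannot show whether the remaining KO transcripts carried the edit.

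**Figure D1:**
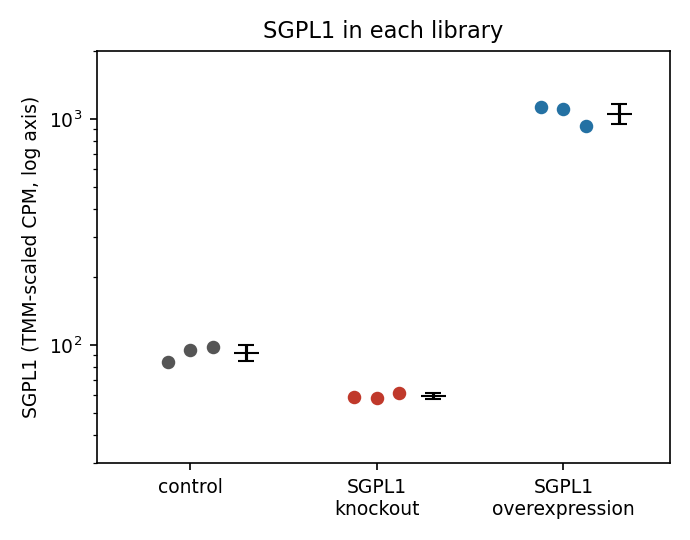
SGPL1 expression in CPM on a log axis, with a point for each of the 9 libraries and the mean ± SD of each group. The KO libraries lie between 58.3 and 61.6 CPM, the control libraries between 83.9 and 98.3 and the OE libraries between 929 and 1132.

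Fold changes in KO cells followed gene length and GC content. Genes in the lowest decile of exon length, with a median of 1178 bases, had a median log2 fold change against control of 0.52, and those in the highest decile, with a median of 13563 bases, one of -0.45. In OE cells the same groups had medians of -0.03 and -0.06. Across genes, which are not independent replicates, the rank correlation of fold change was -0.365 with length and -0.179 with GC content in KO cells, and -0.0445 and 0.0345 in OE cells. All 3 KO libraries carried the trend, with slopes of -0.27, -0.24 and -0.27 log2 units per doubling of length, against -0.05 to 0.03 in control and -0.07 to 0.05 in OE libraries. Every comparison with KO cells was therefore repeated with the trend in each library removed, a correction chosen after seeing the data. Values from that fit are given as "corrected" beside the fitted fold changes and list tests of KO comparisons. For SGPL1 they were -0.45 against control and -3.99 against OE. The correction left decile medians of 0.05 and -0.01.

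**Figure D2:**
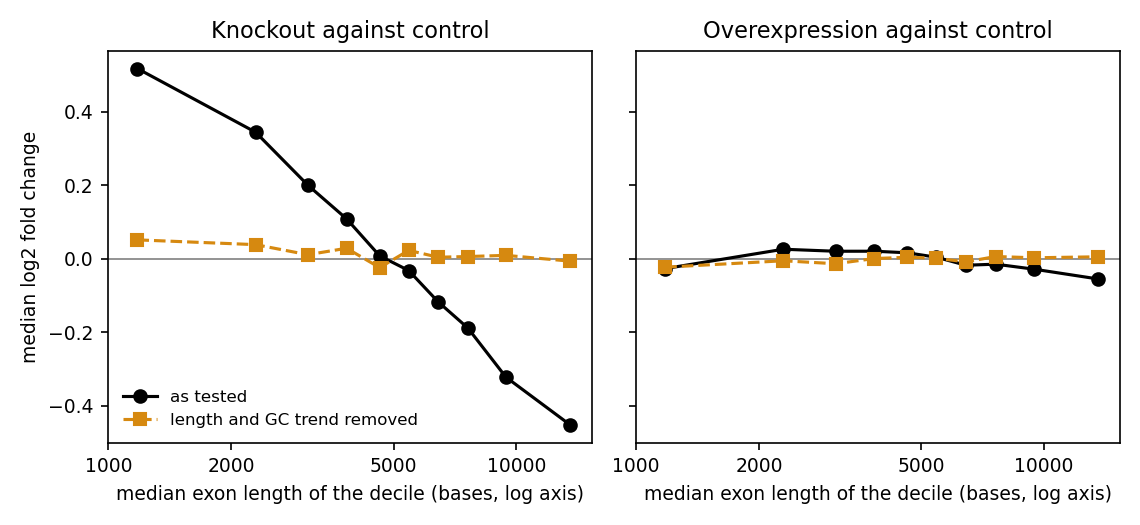
Median log2 fold change of genes in deciles of exon length, with the median length in bases on a log axis, for KO and OE cells against control, before and after removing the trend. The KO medians go from 0.52 to -0.45 and the corrected ones from 0.05 to -0.01.

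The comparison of KO with control cells asked what loss of SGPL1 does to the keratinocyte transcriptome. KO cells had less mRNA for the keratins KRT5, KRT14 and KRT6A, the cornified envelope enzyme TGM1, desmoplakin (DSP) and type VII collagen (COL7A1). They had more for the keratins KRT10 and KRT8, the immediate early genes FOS and EGR1 and for all 40 measured cytosolic ribosomal proteins. Lysosomal genes and targets of the transcription factors NRF2 and p53 were also called higher as lists by camera at its preset correlation. The ribosomal, lysosomal, NRF2 and p53 lists did not pass with an estimated correlation (adjusted p = 0.191, 0.191, 0.191 and 0.143). Fibronectin (FN1) fell from 2626 ± 76.6 to 821 ± 104 CPM, and the lysosomal protease CTSH rose from 48.6 ± 3.41 to 228 ± 17.3 CPM. In all, 6951 of 13390 genes changed, 3485 higher and 3466 lower, of which 851 and 873 changed at least 2-fold. With the length and GC trend removed 6032 genes changed, 3240 higher and 2792 lower. Of the calls, 4703 were shared with the same sign and 70 with the opposite sign. The KO and control libraries did not overlap at 6703 of the 6951 genes, and at 59.5% of all genes, where chance gives 10%.

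The genes that rose most in KO cells were ITGB2, the beta subunit of leukocyte integrins (chromosome 21, 44885953 to 44931989; 0.501 to 6.37 CPM, 3.62 ± 0.52, corrected 4.06), the phosphatase DUSP13 (3.49 ± 0.51, corrected 3.39) and GLDC, the glycine decarboxylase of mitochondria (chromosome 9, 6532467 to 6645729; 3.06 ± 0.21, corrected 3.46). They were followed by the retinol dehydrogenase DHRS9 (3.04 ± 0.31, corrected 2.71), the secreted glycoprotein LRG1 (3.02 ± 0.44, corrected 2.87) and the vesicle exocytosis factor CADPS2 (3.02 ± 0.49, corrected 3.02). FOS and EGR1, transcription factors induced within minutes of growth factor signals, came next (chromosome 14, 75278826 to 75282230 and chromosome 5, 138465479 to 138469303). FOS went from 14.7 ± 0.941 to 110.2 ± 8.73 CPM (2.90 ± 0.12, corrected 2.76) and EGR1 from 14.9 ± 1.14 to 105 ± 8.18 CPM (2.83 ± 0.12, corrected 2.74). The highest adjusted p among these 8 genes was 1.60e-05. Without control replicate 2, ITGB2 had a log2 fold change of 4.21.

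Several genes had no or almost no reads in KO cells. PXDN, a peroxidase that crosslinks collagen IV in basement membranes (ENSG00000130508; chromosome 2, 1631887 to 1744852), had 730 counts over the control libraries and 0 in KO, at least 204-fold lower with the floor at 3 counts over the group. It also had 0 counts in OE, at least 288-fold lower than in control. ARMCX1, a protein of mitochondrial transport (chromosome X, 101550547 to 101554700), had 0 counts in KO and 129 in control, at least 36.1-fold lower. NID2, a nidogen of the basement membrane (chromosome 14, 52004803 to 52069228), had 2 counts against 200, a ratio of 83.9 in favour of control (95% counting interval 22.9 to 698). The other genes of largest fall kept reads: the coactivator EYA2 (-3.26 ± 0.34, corrected -3.24), the sugar transporter SLC2A6 (-3.21 ± 0.29, corrected -3.01), the cytoskeletal protein DPYSL3 (-3.11 ± 0.25, corrected -2.86), the phosphodiesterase PDE1C (-3.00 ± 0.27, corrected -2.67), the keratin-binding epiplakin EPPK1 (-2.82 ± 0.18, corrected -1.78) and the microtubule protein MAP1B (-2.79 ± 0.32, corrected -2.40), with adjusted p values up to 1.50e-07. Intervals and floors cover counting error at most, and less if both mates were counted.

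Around the S1P pathway, single enzymes changed in KO cells without a call for the list by camera. The acid ceramidase ASAH1 rose from 164 ± 15.9 to 279 ± 4.51 CPM (0.77 ± 0.08, corrected 1.05), the S1P phosphatase SGPP1 rose (0.79 ± 0.10, corrected 0.41) and ALDH3A2, which oxidises the aldehyde that S1P lyase releases, went from 155 ± 5.85 to 208 ± 9.91 CPM (0.42 ± 0.08, corrected 0.95), with adjusted p values up to 9.61e-05. The glucosylceramide synthase UGCG rose (0.38 ± 0.09, corrected 0.16, adjusted p = 0.00135, corrected adjusted p = 0.153) and the sphingosine kinase SPHK2 fell (-0.96 ± 0.17, corrected -0.50, adjusted p = 5.40e-05). SPHK1 had 5.35 CPM in control and 4.80 in KO cells (adjusted p = 0.746, corrected 0.599) and the ceramide synthase CERS3 had 50.9 and 53.8 (adjusted p = 0.65, corrected 0.966). Of 44 measured genes of sphingolipid metabolism 18 rose, 6 fell and 20 did not pass (18 and 6 adjusted over the list alone, 15 and 3 once corrected), led upwards by the ceramide synthase CERS4 (2.11 ± 0.27, corrected 2.22). The list did not pass camera (median 0.11, adjusted p = 0.0536, corrected 0.10 and 0.083), but passed without KO replicate 3 (0.0382). It also passed by fry (0.000134). The S1P receptors S1PR1, S1PR2, S1PR3 and S1PR5 had adjusted p values of 0.918, 0.359, 0.989 and 0.129 (corrected 0.863, 0.324, 0.00898 and 0.177). S1PR5 passed without control replicate 2 (0.0207), and S1PR3 had a corrected log2 fold change of 0.53. Among 9 receptors and exporters, the exporter ABCG2 rose (1.16 ± 0.11, corrected 1.04), the exporter ABCC1 fell (-0.57 ± 0.10, corrected -0.18, corrected adjusted p = 0.0932) and 7 did not pass, with the same counts adjusted over the list alone, 2 and 0 once corrected and a list adjusted p of 0.857 (corrected 0.393, and 0.18 by fry). Of 12 genes of phosphoethanolamine lipids and phosphatidylcholine 4 rose and 2 fell (3 and 2 over the list alone, 7 and 1 once corrected). They included the phosphatidylserine synthase PTDSS1 (0.50 ± 0.09, corrected 0.58) and the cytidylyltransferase PCYT1A (-0.55 ± 0.08, corrected -0.34), with adjusted p values up to 5.50e-05 from CERS4 on. That list had adjusted p = 0.454 (corrected 0.0985, and 0.000518 by fry).

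Genes of calcium handling moved in both directions in KO cells. ITPR3, the inositol trisphosphate receptor that releases calcium from the endoplasmic reticulum, fell from 328 ± 26.0 to 108 ± 4.32 CPM (-1.60 ± 0.11, corrected -0.98) and the phospholipase PLCG1 fell (-1.26 ± 0.10, corrected -0.74), whereas calmodulin CALM2 (0.96 ± 0.09, corrected 0.84) and the store leak channel TMCO1 (0.82 ± 0.09, corrected 0.60) rose. ATP2A2, the endoplasmic reticulum calcium pump mutated in Darier disease, was lower (-0.55 ± 0.08, corrected -0.06, corrected adjusted p = 0.491). ATP2C1, the Golgi pump mutated in Hailey-Hailey disease, was higher (0.31 ± 0.08, corrected 0.41, adjusted p = 0.00155). The other genes of this paragraph said to change had adjusted p values up to 2.24e-06. The store sensor STIM1 was lower before the correction (adjusted p = 0.022) and had the opposite sign after it (-0.26 ± 0.09, corrected 0.13, 0.195), and its call was lost without control replicate 2 (0.0669), control replicate 3 (0.0861) or KO replicate 3 (0.128). Its partner channel ORAI1 had 0.23 ± 0.15, corrected 0.14 (adjusted p = 0.202, corrected 0.495). Of 36 genes of calcium stores and channels 14 rose, 11 fell and 11 did not pass (14 and 12 adjusted over the list alone, 13 and 7 once corrected), and the list did not pass (adjusted p = 0.91, corrected 0.539). The list of S100 calcium-binding proteins was called higher before the correction only, with 9 of 13 higher and 1 lower (10 and 2 adjusted over the list alone, 5 and 4 once corrected). S100A9, a subunit of the antimicrobial calprotectin, went from 34.7 ± 2.58 to 246 ± 33.4 CPM (2.82 ± 0.13, corrected 2.17) and S100A6 from 373 ± 63.6 to 1029.7 ± 92.3 (1.47 ± 0.11, corrected 1.01). S100 genes are short, and the list's median went from 0.39 to -0.03 with the trend removed (adjusted p = 0.000968, corrected 0.359, and 0.407 with an estimated correlation).

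Basal and junction genes went both ways in KO cells. The basal keratins KRT5 and KRT14 went from 11016 ± 178 to 5849.8 ± 522 CPM (-0.91 ± 0.08, corrected -0.81) and from 5453 ± 174 to 2929 ± 109 (-0.90 ± 0.08, corrected -1.03). Of 27 basal and hemidesmosome genes 8 rose, 13 fell and 6 did not pass (8 and 13 adjusted over the list alone, 8 and 9 once corrected). The anchoring fibril collagen COL7A1 (-2.44 ± 0.11, corrected -1.65), plectin PLEC (-1.99 ± 0.12, corrected -0.96) and the laminin chain LAMA5 (-1.26 ± 0.10, corrected -0.32) were among the falls. These are genes of long transcripts, and the list was called before the correction (median -0.19, adjusted p = 0.0162) but not after it (0.01, 0.38) or with an estimated correlation (adjusted p = 0.324). Among 33 genes of desmosomes, adherens and tight junctions 7 rose, 16 fell and 10 did not pass (7 and 16 adjusted over the list alone, 5 and 10 once corrected). DSP, the desmosomal plaque protein, went from 2024 ± 126 to 682 ± 56.3 CPM (-1.57 ± 0.10, corrected -1.21), the tight junction protein cingulin CGN fell (-1.96 ± 0.12, corrected -1.62) and plakoglobin JUP fell (-0.87 ± 0.08, corrected -0.56), with an adjusted p of at most 3.91e-09 for the genes of keratin, matrix and junction named. That list too was called only before the correction (median -0.33, adjusted p = 0.012, corrected 0.083, and 0.431 with an estimated correlation).

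TGM1, the transglutaminase that crosslinks the cornified envelope and is mutated in lamellar ichthyosis, fell from 85.6 ± 5.21 to 25.8 ± 2.92 CPM (-1.72 ± 0.11, corrected -1.63, adjusted p = 1.11e-11). The envelope plakins EVPL (-1.62 ± 0.10, corrected -1.03) and PPL (-1.48 ± 0.10, corrected -0.99) fell as well, whereas the desquamation protease KLK5 (0.84 ± 0.08, corrected 0.52) and the suprabasal keratin KRT10 (0.90 ± 0.11, corrected 0.56) rose. Involucrin (IVL) had 99.1 ± 6.16 CPM in control and 111 ± 12.1 in KO cells (adjusted p = 0.175, corrected 0.745). KRT1, FLG, LORICRIN and the S1P phosphatase SGPP2 were too low to test, with 0, 10, 0 and 3 counts over the control libraries and 2, 2, 0 and 6 over the KO libraries. Of 22 cornification genes 7 rose, 5 fell and 10 did not pass (7 and 5 adjusted over the list alone, 6 and 7 once corrected; median 0.22, mean 0.08, test downwards, adjusted p = 0.91, corrected 0.178). Of 32 barrier lipid and ichthyosis genes 16 rose, 8 fell and 8 did not pass (17 and 8 adjusted over the list alone, 11 and 8 once corrected). Among them were the sulfatase-modifying factor SUMF1 (0.90 ± 0.09, corrected 1.08) and the cholesterol sulfotransferase SULT2B1 (-1.14 ± 0.13, corrected -1.19). That list did not pass either (adjusted p = 0.772, corrected 0.945). Of 21 wound and stress genes 8 rose, 8 fell and 5 did not pass (8 and 8 adjusted over the list alone, 5 and 10 once corrected). The hyperproliferation keratin KRT6A fell from 7107 ± 158 to 2357 ± 231 CPM (-1.59 ± 0.08, corrected -1.71) and its near-identical copy KRT6B fell (-2.17 ± 0.20, corrected -2.39), though reads shared by the pair make both uncertain. The iron-binding lipocalin LCN2 rose (2.35 ± 0.14, corrected 1.99). For the genes from EVPL to LCN2 that changed, adjusted p was at most 6.70e-07. Median 0.06 and mean 0.20 of that list were positive and its test pointed downwards, as did the corrected median of -0.01 (adjusted p = 0.936, corrected 0.083).

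Both enzymes that build palmitate from acetyl-CoA fell in KO cells. Fatty acid synthase FASN went from 1955 ± 214 to 585 ± 14.5 CPM (-1.74 ± 0.09, corrected -1.02) and the acetyl-CoA carboxylase ACACA from 269.9 ± 15.5 to 115 ± 11.1 (-1.23 ± 0.09, corrected -0.73). Of 25 fatty acid genes 8 rose, 9 fell and 8 did not pass (8 and 10 adjusted over the list alone, 5 and 9 once corrected). Of 25 cholesterol genes 8 rose, 10 fell and 7 did not pass (9 and 10 adjusted over the list alone, 4 and 8 once corrected). These included squalene epoxidase SQLE (-0.69 ± 0.09, corrected -0.82), which fell (adjusted p up to 9.76e-07 for the genes named). In both lists the median was positive (0.13 and 0.10), the mean negative (-0.13 and -0.11) and the test downwards without passing (adjusted p = 0.202 and 0.42, corrected 0.129 and 0.205).

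All 40 measured cytosolic ribosomal protein genes rose in KO cells, with the same count adjusted over the list alone and with the trend removed. The acidic stalk protein RPLP0 went from 1907 ± 143 to 5228 ± 379 CPM (1.46 ± 0.09, corrected 1.39) and RPS3 from 1408 ± 66.1 to 3804 ± 216 (1.43 ± 0.10, corrected 1.43). The median log2 fold change of the list was 1.15 (camera adjusted p = 3.15e-42), corrected 1.05 (1.04e-51), and adjusted p = 0.191 with an estimated correlation. The correction used the length of all annotated exons, so it may remove too little for these genes. Mitochondrially encoded mRNAs fell, 12 of 13 (12 adjusted over the list alone, 13 once corrected), with the complex I subunit MT-ND4 going from 2708 ± 186 to 1119 ± 312 CPM (-1.28 ± 0.13, corrected -1.83). Their median was -0.98 (adjusted p = 1.55e-06), corrected -1.69 (1.25e-24), and adjusted p = 0.349 with an estimated correlation. The share of counts on the mitochondrial genome was 0.889%, 1.25% and 1.39% in KO libraries, 1.84%, 2.00% and 2.04% in control and 1.22%, 1.41% and 1.39% in OE libraries. Replication-dependent histone genes, whose mRNAs mostly lack the poly-A tail that the library selects, had 10 of 15 higher and 0 lower (11 and 0 adjusted over the list alone, 4 and 0 once corrected), among them H2AC6 (1.49 ± 0.12, corrected 0.96) and H1-2 (1.66 ± 0.17, corrected 1.08), and the genes named here had adjusted p up to 2.83e-08. Their list was called before the correction (median 1.04, adjusted p = 0.00216) and not after it (0.51, 0.129) or with an estimated correlation (adjusted p = 0.222). Ribosomal protein, histone and mitochondrial genes have near-identical copies elsewhere in the genome, so shared reads make each level uncertain.

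Of 44 lysosomal genes 20 rose, 3 fell and 21 did not pass (20 and 4 adjusted over the list alone, 24 and 2 once corrected) in KO cells. CTSH had 2.23 ± 0.10, corrected 2.44, the cholesterol carrier NPC2 1.28 ± 0.09, corrected 0.87, the tetraspanin CD63 1.13 ± 0.08, corrected 0.89 and the thioesterase PPT1 0.98 ± 0.09, corrected 0.71. The median was 0.22 (adjusted p = 0.000492), corrected 0.42 (7.14e-08), and adjusted p = 0.191 with an estimated correlation. Of 26 NRF2 targets 17 rose, 2 fell and 7 did not pass (17 and 2 adjusted over the list alone, 13 and 2 once corrected). The quinone reductase NQO1 went from 81.9 ± 5.35 to 181 ± 18.4 CPM (1.14 ± 0.09, corrected 0.82), and the aldo-keto reductase AKR1C3 (1.55 ± 0.09, corrected 1.26) and ferritin FTH1 (0.73 ± 0.08, corrected 0.33) also rose, both with close copies that share reads. The list's median was 0.37 (adjusted p = 0.000275), corrected 0.25 (0.00249), and adjusted p = 0.191 with an estimated correlation. Of 29 p53 targets 15 rose, 4 fell and 10 did not pass (15 and 4 adjusted over the list alone, 15 and 3 once corrected). They were led by the stress cytokine GDF15 (25.9 ± 5.01 to 83.9 ± 5.12 CPM, 1.69 ± 0.13, corrected 1.58) and the death receptor FAS (1.24 ± 0.12, corrected 1.07), the adjusted p of the genes named being 3.32e-08 or less. Their median was 0.31 (adjusted p = 0.00327), corrected 0.27 (0.00639), and adjusted p = 0.143 with an estimated correlation.

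Of 49 cell cycle genes 15 rose, 15 fell and 19 did not pass (15 and 15 adjusted over the list alone, 5 and 12 once corrected) in KO cells. The mitotic motor CENPE (-1.85 ± 0.13, corrected -1.82), the proliferation marker MKI67 (171 ± 15.5 to 63.5 ± 8.87 CPM, -1.43 ± 0.11, corrected -0.95) and CENPF (-1.02 ± 0.12, corrected -0.76) fell and survivin BIRC5 rose (1.16 ± 0.12, corrected 1.11), with a positive median of 0.09, a corrected one of -0.08 and a test pointing downwards (adjusted p = 0.992, corrected 0.138). Of 31 unfolded protein response genes 12 rose, 4 fell and 15 did not pass (12 and 4 adjusted over the list alone, 9 and 8 once corrected). Members that changed were the disulfide isomerase PDIA6 (0.59 ± 0.08, corrected 0.42), the pseudokinase TRIB3 (1.10 ± 0.16, corrected 1.14) and the chaperone HYOU1 (-0.61 ± 0.09, corrected -0.21; list adjusted p = 0.501, corrected 0.948). Hypoxia and glycolysis genes were called higher as a list only with the trend removed (adjusted p = 0.00024 against 0.0908 before, and 0.225 with the trend removed and an estimated correlation), or without KO replicate 2 (0.0374). Of 30 measured 14 rose, 7 fell and 9 did not pass (16 and 7 adjusted over the list alone, 20 and 4 once corrected). The vasodilator peptide ADM went from 39.2 ± 3.07 to 95.3 ± 7.51 CPM (1.29 ± 0.10, corrected 1.12) and the glycolytic enzyme GAPDH from 2633 ± 249.6 to 4448 ± 490.2 (0.76 ± 0.09, corrected 0.61). Adjusted p was at most 3.75e-06 for these cycle, stress and glycolysis genes.

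Of 18 class I antigen presentation genes 9 rose, 1 fell and 8 did not pass (9 and 1 adjusted over the list alone, 9 and 1 once corrected) in KO cells. The light chain B2M went from 267 ± 29.3 to 668 ± 15.6 CPM (1.32 ± 0.09, corrected 1.23) and the immunoproteasome subunit PSMB8 from 33.5 ± 4.34 to 92.3 ± 8.99 (1.46 ± 0.12, corrected 1.40), while HLA-C (0.45 ± 0.07, corrected 0.42) is uncertain because HLA genes share reads. The list had a median of 0.27 (adjusted p = 0.0308), corrected 0.24 (0.0469), and adjusted p = 0.191 with an estimated correlation. Interferon-stimulated genes split, with 6 of 34 higher and 6 lower (5 and 5 adjusted over the list alone, 4 and 4 once corrected; list adjusted p = 0.857, corrected 0.823), such as the antiviral IFITM2 (1.88 ± 0.19, corrected 1.49) and, among the falls, OAS3 (63.5 ± 4.14 to 31.7 ± 2.17 CPM, corrected -0.58). Of 17 inflammatory cytokines and NF-kB targets 7 rose, 1 fell and 9 did not pass (7 and 1 adjusted over the list alone, 6 and 1 once corrected). The alarmin IL33 went from 2.50 ± 0.219 to 16.1 ± 0.737 CPM (2.68 ± 0.26, corrected 2.21), the cytokine IL18 rose (0.95 ± 0.09, corrected 0.47) and the cyclooxygenase PTGS2 rose (1.03 ± 0.10, corrected 0.78), and the immune genes named had adjusted p up to 1.74e-05. This list had a median of 0.36 and missed the threshold (adjusted p = 0.0536, corrected 0.117), but passed without control replicate 2 (0.0409), KO replicate 3 (0.0382) or OE replicate 1 (0.0491).

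Of 30 genes of matrix and epithelial-mesenchymal transition 7 rose, 18 fell and 5 did not pass (7 and 18 adjusted over the list alone, 6 and 14 once corrected) in KO cells. Thrombospondin THBS1 (-1.74 ± 0.10, corrected -1.49), FN1 (-1.68 ± 0.10, corrected -1.21) and the basement membrane collagen COL4A2 (-1.42 ± 0.08, corrected -0.45) fell, and the collagen-binding protein SPARC rose from 87.5 ± 4.76 to 241 ± 1.93 CPM (1.46 ± 0.08, corrected 1.39). The list's median was -0.50 (adjusted p = 0.000542), corrected -0.26 (0.0153), and adjusted p = 0.133 with an estimated correlation. Of 24 YAP and TEAD targets 5 rose, 13 fell and 6 did not pass (5 and 13 adjusted over the list alone, 4 and 11 once corrected). The membrane repair protein MYOF was lower (-1.11 ± 0.09, corrected -0.88) and the growth factor carrier IGFBP3 higher (1.25 ± 0.16, corrected 1.23). That call (median -0.43, adjusted p = 0.0308) ended with the trend removed (-0.29, 0.0938) and with an estimated correlation (adjusted p = 0.324). Of 30 EGFR, MAPK and immediate early genes 8 rose, 4 fell and 18 did not pass (8 and 4 adjusted over the list alone, 7 and 4 once corrected). The receptor EGFR itself fell (-0.71 ± 0.09, corrected -0.26). Their list pointed upwards (median 0.18) with adjusted p = 0.0536 (corrected 0.0938) and passed without control replicate 2 (0.0409), control replicate 3 (0.0357), KO replicate 1 (0.036) or KO replicate 3 (0.0407). Of 16 Notch genes 2 rose, 8 fell and 6 did not pass (2 and 8 adjusted over the list alone, 3 and 1 once corrected; median -0.31, corrected 0.10; list adjusted p = 0.42, corrected 0.685). The receptors NOTCH1 (-0.77 ± 0.10, corrected -0.03) and NOTCH3 (-0.63 ± 0.10, corrected 0.05) fell before the correction only (corrected adjusted p = 0.782 and 0.626), and NOTCH3 changed sign. Before the correction, adjusted p was at most 2.13e-05 for the matrix and signalling genes named. Of the genes named for KO cells, PTGS2 and CENPF lie in a part of chromosome 1 where neighbouring genes were together higher (median 0.41, corrected, over 313 genes, and 0.12 in OE cells).

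Camera called 12 of 31 lists in KO against control, 7 higher and 5 lower, and 8 with the trend removed. With an estimated correlation 0 lists passed, although 7 had an unadjusted p under 0.05 and fry called 20. With the trend removed the lowest adjusted p was 0.108 with an estimated correlation, for lysosomal genes.

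**Figure D3:**
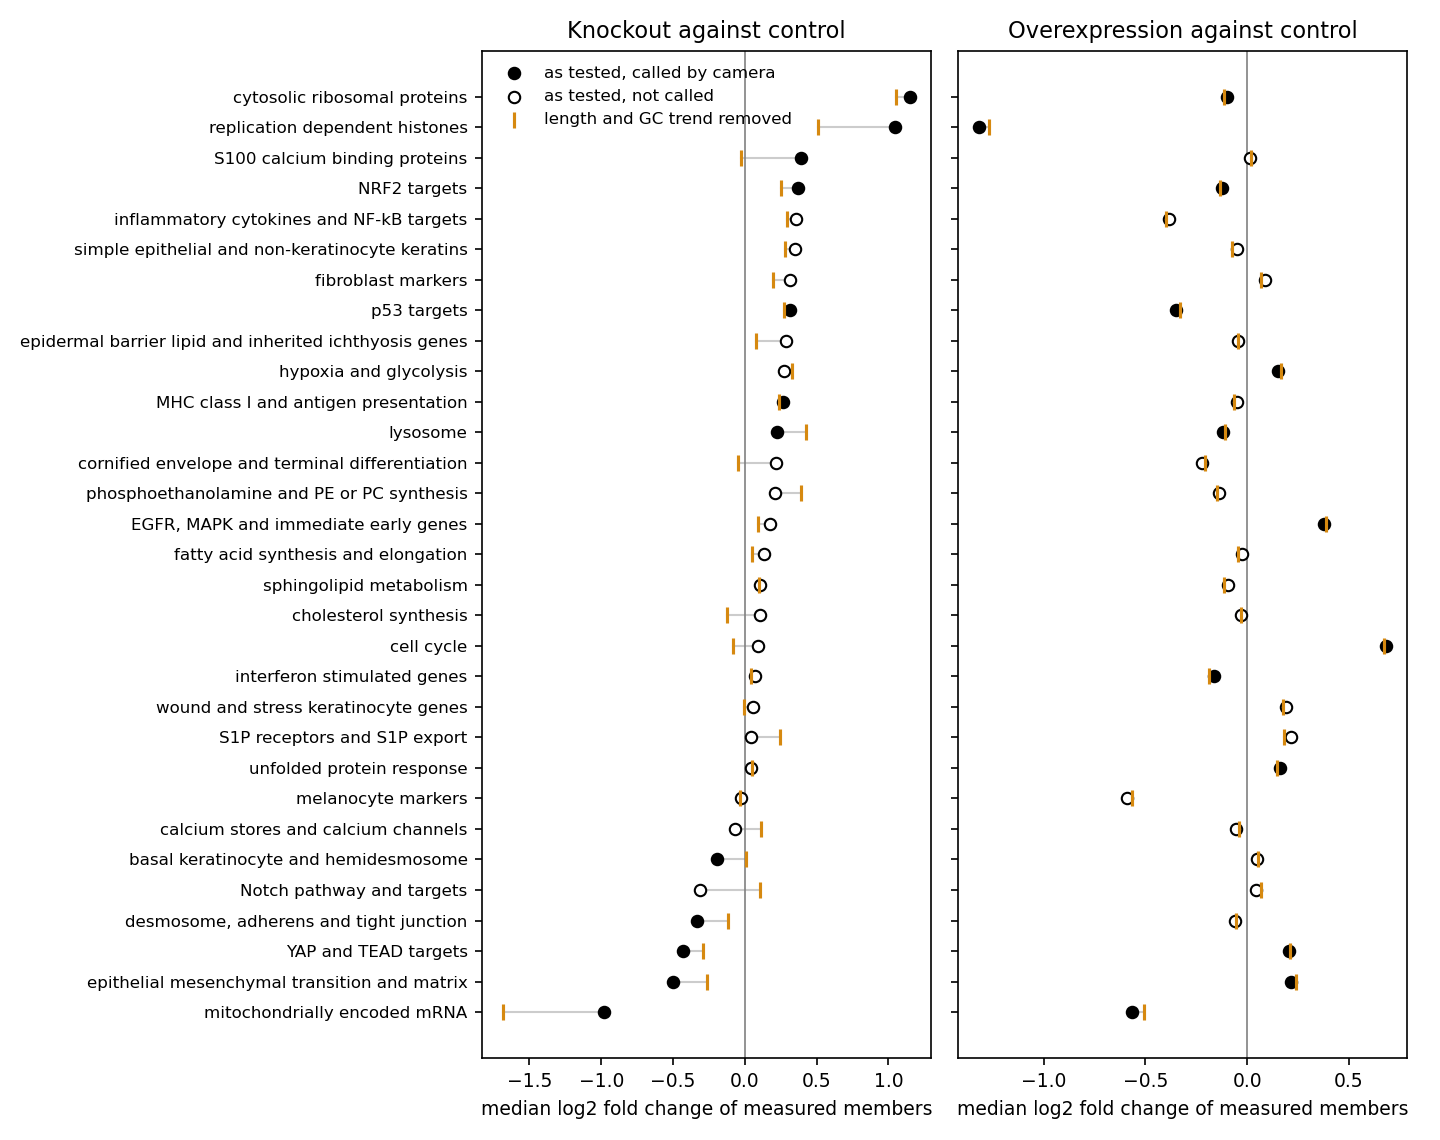
Median log2 fold change of each gene list fixed before the data were examined, in KO and OE cells against control, with filled points for lists called by camera with its preset correlation and open points for the others. Orange ticks give the medians of each panel with the length and GC trend removed. In KO cells the ribosomal protein list lies at 1.15 before and 1.05 after removal.

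The comparison of OE with control cells asked what an excess of SGPL1 does. At its preset correlation, camera called genes of the cell cycle, of EGFR and MAPK signalling, of YAP and of matrix higher and p53 targets, replication-dependent histones and mitochondrially encoded mRNAs lower. Of these only the p53 call held with an estimated correlation, where the others had adjusted p = 0.0653, 0.0694, 0.114, 0.0694, 0.0653 and 0.282 in that order. MYBL2, a transcription factor of dividing cells, rose from 89.0 ± 1.99 to 206 ± 14.3 CPM, and the p53 target TP53INP1 fell from 60.4 ± 4.05 to 25.5 ± 3.82 CPM. Against control 2493 genes changed, 1242 higher and 1251 lower, of which 196 and 255 changed at least 2-fold. The OE and control libraries did not overlap at 2425 of these genes, and at 34.8% of all genes, where chance gives 10%. Removing a trend with length and GC left 2437 of the calls, with the same sign, among 2804.

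SGPL1 was among the largest rises, along with epsilon-sarcoglycan SGCE (chromosome 7, 94524204 to 94656572; 4.13 ± 0.58) and the imprinted gene PEG10 next to it (chromosome 7, 94656325 to 94669695; 1.96 ± 0.399 to 16.6 ± 1.48 CPM, 3.08 ± 0.27). The others were the peptide hormone ADM2 (2.86 ± 0.48), CADPS2 (2.83 ± 0.48), the ubiquitin ligase MARCHF4 (2.71 ± 0.30), the connexin GJB6 (2.60 ± 0.41) and the LIM protein FHL1 (2.54 ± 0.30). Without control replicate 3, ADM2 had 3.61. Besides PXDN, with 0 counts in OE, the largest falls were BCAS1 (-4.15 ± 0.54), the extracellular superoxide dismutase SOD3 (chromosome 4, 24789912 to 24800842; 22.7 ± 3.62 to 1.33 ± 0.432 CPM, -4.09 ± 0.24) and the small heat shock protein HSPB8 (chromosome 12, 119171555 to 119224855; 52.2 ± 4.94 to 4.65 ± 1.28 CPM, -3.50 ± 0.17). The matricellular protein CCN5 (-3.16 ± 0.42), the ubiquitin ligases TRIM31 (-2.87 ± 0.31) and FBXO32 (-2.50 ± 0.23) and the basement membrane protein FRAS1 (-2.63 ± 0.33) followed. BCAS1 had -5.52 without OE replicate 3, and the adjusted p values of these genes went up to 0.000171.

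Of 49 cell cycle genes 45 rose, 0 fell and 4 did not pass (48 and 0 adjusted over the list alone) in OE cells. MYBL2 had a log2 fold change of 1.21 ± 0.08, the ribonucleotide reductase subunit RRM2 1.05 ± 0.10 and the replication helicase subunit MCM7 0.75 ± 0.08. The median was 0.68 (camera adjusted p = 2.03e-42, and 0.0653 with an estimated correlation). Of 29 p53 targets 3 rose, 16 fell and 10 did not pass (3 and 18 adjusted over the list alone). TP53INP1 had -1.26 ± 0.12, RRM2B, which supplies nucleotides for repair, -0.80 ± 0.09 and the antiproliferative BTG2 -0.74 ± 0.09. Their median was -0.35 (adjusted p = 3.23e-08), and this call held with an estimated correlation (adjusted p = 0.0179). Of 15 histone genes 9 fell (10 adjusted over the list alone), such as H2AC6 (-1.47 ± 0.14; list median -1.32, adjusted p = 4.33e-10, and 0.0653 with an estimated correlation). All 13 mitochondrially encoded mRNAs fell, also over the list alone, such as cytochrome b MT-CYB (-0.75 ± 0.12; list median -0.57, adjusted p = 3.38e-09, and 0.282 with an estimated correlation). Ribosomal protein genes were called slightly lower (median -0.10, adjusted p = 0.0478, and 0.771 with an estimated correlation), although 1 of 40, RPS28 (-0.30 ± 0.09), fell and 0 did over the list alone. That call was lost without control replicate 1 (0.495), KO replicate 3 (0.0505), OE replicate 1 (0.314) or OE replicate 2 (0.533), and fry gave it 0.422. RPS28 was lost without control replicate 1 (0.227), control replicate 2 (0.0508) or OE replicate 2 (0.151). Copies of histone, ribosomal and mitochondrial genes share reads, which leaves their levels uncertain. Apart from RPS28 (0.0269), the genes named here had adjusted p up to 0.000121.

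Of 30 EGFR, MAPK and immediate early genes 17 rose, 1 fell and 12 did not pass (17 and 1 adjusted over the list alone) in OE cells, among them PHLDA1 (1.09 ± 0.10), the EGFR ligand AREG (79.6 ± 4.46 to 139 ± 33.6 CPM, 0.81 ± 0.12) and EGR1 (0.78 ± 0.12; list median 0.38, adjusted p = 1.31e-08, and 0.0694 with an estimated correlation). Of 24 YAP and TEAD targets 8 rose, 0 fell and 16 did not pass (8 and 0 adjusted over the list alone), including tissue factor F3 (1.07 ± 0.11) and the matricellular CCN1 (0.84 ± 0.13; list median 0.21, adjusted p = 0.000535, and 0.114 with an estimated correlation). Among 30 matrix and transition genes 10 rose, 4 fell and 16 did not pass (10 and 5 adjusted over the list alone). THBS1 rose from 383 ± 23.1 to 1055 ± 125 CPM (1.46 ± 0.10), FN1 from 2626 ± 76.6 to 4039 ± 499 (0.62 ± 0.09) and the fibronectin receptor ITGA5 also rose (0.73 ± 0.08), while the collagen COL16A1 fell (-1.28 ± 0.14; list median 0.22, adjusted p = 0.00569, and 0.0694 with an estimated correlation). Notch genes barely moved, 1 of 16 lower, NOTCH3 (-0.64 ± 0.10), with the same count over the list alone (median 0.04, test downwards, adjusted p = 0.848). Named genes of growth signalling and matrix had adjusted p up to 8.27e-05.

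Of 31 unfolded protein response genes 6 rose, 2 fell and 23 did not pass (8 and 2 adjusted over the list alone), with the serine synthesis enzyme PSAT1 going from 85.5 ± 4.03 to 284 ± 51.2 CPM (1.73 ± 0.10; list median 0.16, adjusted p = 0.0141, and 0.0877 with an estimated correlation). Of 30 hypoxia and glycolysis genes 8 rose, 2 fell and 20 did not pass (10 and 3 adjusted over the list alone), such as NDRG1 (1.12 ± 0.14) and the angiogenic factor VEGFA (0.66 ± 0.13; list median 0.15, adjusted p = 0.0155, and 0.282 with an estimated correlation). NRF2 targets were called lower, with 3 of 26 higher and 11 lower (4 and 11 adjusted over the list alone). The exporter ABCC2 (-1.72 ± 0.11) and the glutathione peroxidase GPX2 (-1.26 ± 0.13) fell, and both chains of the cystine importer, SLC7A11 (14.5 ± 0.477 to 82.0 ± 15.9 CPM, 2.50 ± 0.15) and SLC3A2 (0.86 ± 0.08), rose. That list had a median of -0.12 (adjusted p = 0.00211, and 0.228 with an estimated correlation). Of 44 lysosomal genes 1 rose, 9 fell and 34 did not pass (2 and 11 adjusted over the list alone), with CTSH (-0.83 ± 0.11) and the saposin precursor PSAP (-0.49 ± 0.08) lower (list median -0.12, adjusted p = 0.0483, and 0.298 with an estimated correlation). The lysosome call was lost without control replicate 2 (0.0741), control replicate 3 (0.0642), KO replicate 2 (0.0562), KO replicate 3 (0.0579) or OE replicate 2 (0.125). Desaturase FADS1 fell from 51.6 ± 0.434 to 18.1 ± 1.84 CPM (-1.52 ± 0.11) and acyl-CoA synthetase ACSL3 rose (0.73 ± 0.07). Of 25 fatty acid genes 2 rose, 6 fell and 17 did not pass (2 and 6 adjusted over the list alone; list adjusted p = 0.0927). Of 25 cholesterol genes 5 rose, 5 fell and 15 did not pass (5 and 5 adjusted over the list alone; list adjusted p = 0.719). Adjusted p of the stress and lipid genes named was at most 0.000693.

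In the S1P pathway of OE cells, ASAH1 fell from 164 ± 15.9 to 133 ± 6.92 CPM (-0.30 ± 0.08, adjusted p = 0.0128), a call lost without control replicate 1 (0.12) or OE replicate 2 (0.0781) and once corrected (0.0529), and so did SGPP1 (-0.39 ± 0.10, adjusted p = 0.00722), lost without OE replicate 2 (0.0516). CERS3 fell (-0.79 ± 0.14, adjusted p = 0.000244). SPHK1 (adjusted p = 0.308), SPHK2 (0.659), UGCG (0.111), ALDH3A2 (0.0644) and the receptors S1PR1 (0.178), S1PR2 (0.217), S1PR3 (0.349) and S1PR5 (0.362) did not pass. Of 44 sphingolipid genes 3 rose, 9 fell and 32 did not pass (3 and 11 adjusted over the list alone; list adjusted p = 0.209). Of 9 receptors and exporters 0 rose, 1 fell and 8 did not pass (0 and 1 adjusted over the list alone; list adjusted p = 0.514), and the fall, of ABCA1 (adjusted p = 0.0143), was lost without control replicate 3 (0.126). Of 12 genes of phosphoethanolamine lipids and phosphatidylcholine 1 rose, 2 fell and 9 did not pass (1 and 2 adjusted over the list alone; list adjusted p = 0.42). These 3 calls (PEMT, PCYT1A and ETNK1) were lost without any 1 of the control libraries (adjusted p from 0.0658 to 0.138) or without OE replicate 2 (0.0659 to 0.134). PEMT and ETNK1 were also lost without OE replicate 3 (0.159 and 0.157) and once corrected (0.0501 and 0.0518), PEMT with the replicate as a block (0.0519) and ETNK1 without KO replicate 2 (0.0587). In calcium handling 4 of 36 rose and 4 fell (6 and 6 adjusted over the list alone; list adjusted p = 0.804), such as the secretory pathway pump ATP2C2 (1.11 ± 0.18, adjusted p = 0.000112). ATP2A2 (adjusted p = 0.993), ATP2C1 (0.604), STIM1 (0.219) and ORAI1 (0.41 ± 0.15, 0.054) did not pass, though ORAI1 did without KO replicate 3 (0.0482) or OE replicate 1 (0.0443). S100P (-0.86 ± 0.10) and S100A6 (-0.81 ± 0.11) fell (adjusted p up to 1.49e-05), and the S100 list, with the same 2 of 13 lower over the list alone, was called only without OE replicate 3 (0.00388 against 0.217; median 0.01, mean -0.11).

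Keratinocyte genes changed in part in OE cells. KRT14 rose from 5453 ± 174 to 7199 ± 529 CPM (0.40 ± 0.08, adjusted p = 0.000466), while KRT5 had -0.03 ± 0.08 (adjusted p = 0.854). Of 27 basal genes 9 rose, 3 fell and 15 did not pass (10 and 4 adjusted over the list alone). The integrins ITGA6 (0.40 ± 0.08) and ITGB4 (0.51 ± 0.08) were higher and the basal keratin KRT15 lower (-0.99 ± 0.10). The list had adjusted p = 0.158, and 0.0148 without OE replicate 3. TGM1 (0.32 ± 0.09, adjusted p = 0.019) rose, and IVL (-0.33 ± 0.10, 0.0202) and KRT10 (-0.36 ± 0.12, 0.0318) fell. TGM1 was lost without control replicate 2 (0.0506), control replicate 3 (0.109), OE replicate 1 (0.0628) or OE replicate 2 (0.0648). IVL was lost without control replicate 1 (0.107), control replicate 2 (0.0672) or OE replicate 3 (0.0968). KRT10 was lost without control replicate 1 (0.158), control replicate 2 (0.0954) or OE replicate 2 (0.177). KRT1, FLG, LORICRIN and SGPP2 had 4, 0, 0 and 0 counts over the OE libraries. Of the 22 measured cornification genes 3 rose, 7 fell and 12 did not pass (3 and 7 adjusted over the list alone, list adjusted p = 0.233). The envelope precursor SPRR1B was higher (0.92 ± 0.17) and KLK7 lower (-0.50 ± 0.12). Of 32 barrier genes 5 rose, 6 fell and 21 did not pass (6 and 7 adjusted over the list alone; median -0.05, mean 0.11, adjusted p = 0.804). The connexin GJB2 went from 26.1 ± 3.34 to 95.1 ± 17.8 CPM (1.87 ± 0.13) and the lipid transporter ABCA12 from 249 ± 4.10 to 162 ± 23.9 (-0.62 ± 0.09). Of 21 wound genes 8 rose, 4 fell and 9 did not pass (9 and 4 adjusted over the list alone; list adjusted p = 0.0989). Of 33 junction genes 4 rose, 4 fell and 25 did not pass (4 and 6 adjusted over the list alone; list adjusted p = 0.28). From ITGA6 to ABCA12, other than TGM1, IVL and KRT10, adjusted p was at most 0.0047.

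Of 34 interferon-stimulated genes 0 rose, 7 fell and 27 did not pass (0 and 7 adjusted over the list alone) in OE cells, such as TRIM22 (-0.96 ± 0.11). The list was called lower (median -0.16, adjusted p = 0.0286, and 0.228 with an estimated correlation), but not without control replicate 1 (0.0698) or OE replicate 2 (0.0777). Of 17 inflammatory genes 3 rose, 6 fell and 8 did not pass (3 and 6 adjusted over the list alone; list adjusted p = 0.28): PTGS2 (1.00 ± 0.10) and the cytokine IL1A (1.58 ± 0.21) rose and the NF-kB target TNFAIP2 fell (-1.48 ± 0.16). Class I genes had 1 of 18 lower, the peptide trimming enzyme ERAP2 (-0.39 ± 0.09), with the same count over the list alone (median -0.05, mean 0.01, test downwards, adjusted p = 0.804). These immune genes had adjusted p up to 0.00377. Camera called 13 of 31 lists in OE against control, 6 higher and 7 lower, of which 1, the p53 targets, passed with an estimated correlation. With the trend removed 6 passed at an estimated correlation: cell cycle, matrix, EGFR and histone genes (adjusted p = 0.0426 each), YAP targets (0.0476) and p53 targets (0.0235).

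KO and OE cells, the ends of the SGPL1 range, were compared in the same fit of all libraries. Camera called cell cycle, YAP target and matrix genes lower in KO than in OE cells, and p53 targets, NRF2 targets, lysosomal, ribosomal protein and histone genes higher. The matrix and p53 calls held with an estimated correlation, where cell cycle, YAP, NRF2, lysosomal, ribosomal and histone genes had adjusted p = 0.261, 0.0927, 0.086, 0.086, 0.124 and 0.0506. THBS1 had 115 ± 16.2 CPM in KO and 1055 ± 125 in OE cells (-3.21 ± 0.10, corrected -2.99), MKI67 had 63.5 ± 8.87 and 279.8 ± 43.3 (-2.14 ± 0.11, corrected -1.70) and CTSH had 228 ± 17.3 and 27.3 ± 3.53 (3.06 ± 0.10, corrected 3.27), all with adjusted p up to 4.30e-13. In all 7711 genes changed, 3824 higher and 3887 lower in KO, of which 1269 and 1199 at least 2-fold, and a fit of these groups alone gave 7355. With the trend removed 7131 changed, 5801 of them shared with the same sign and 52 with the opposite sign. Libraries of the groups did not overlap at 7269 of the 7711 genes, and at 61.6% of all genes, where chance gives 10%.

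The largest rises in KO over OE cells were RCSD1 (5.38 ± 0.60, corrected 5.71), the diamine oxidase AOC1 (5.20 ± 0.40, corrected 5.36), GLDC (4.70 ± 0.24, corrected 5.06), IL33 (4.33 ± 0.30, corrected 3.89), the homeodomain protein HOPX (37.6 ± 4.92 against 1.89 ± 0.594 CPM, 4.28 ± 0.25, corrected 4.33), BCAS1 (4.23 ± 0.54, corrected 4.38), the deiminase PADI3 (4.21 ± 0.38, corrected 4.18) and CLCA4 (4.15 ± 0.23, corrected 3.78). Without a library of OE, RCSD1 had 6.98 (replicate 1), AOC1 5.96 (replicate 2) and BCAS1 5.61 (replicate 3). The largest falls included genes with at most 3 counts over the KO libraries. ARMCX1 had 0 counts in KO and 349 in OE, at least 82.4-fold lower, and SGCE 0 and 173, at least 40.8-fold lower. PEG10 had 2 and 542 counts, a ratio of 192 in favour of OE (counting interval 52.9 to 1588), TBL1X (chromosome X, 9463295 to 9741037) 2 and 345 (122, 33.6 to 1013), NID2 2 and 233 (82.5, 22.6 to 685) and the collagen hydroxylase P3H3 (chromosome 12, 6828407 to 6839847) 3 and 202 (47.7, 16.1 to 233). Both counts of PEG10 and of TBL1X came from KO replicate 1, both of NID2 from KO replicate 2, and P3H3 had 0, 1 and 2 in KO replicates 1 to 3. FHL1 (-5.08 ± 0.42, corrected -5.10) and PDE1C (-4.62 ± 0.25, corrected -4.35) completed the falls. The highest adjusted p of the genes with a fitted fold here was 4.90e-07.

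Of the fixed genes, ASAH1 (1.07 ± 0.08, corrected 1.28), SGPP1 (1.18 ± 0.10, corrected 0.82), CERS3 (0.86 ± 0.14, corrected 0.79), ALDH3A2 (0.63 ± 0.08, corrected 1.10), KRT10 (1.26 ± 0.12, corrected 0.94), IVL (0.49 ± 0.10, corrected 0.32) and ATP2C1 (0.37 ± 0.08, corrected 0.45) were higher in KO than in OE cells, with adjusted p up to 0.000184. SPHK2 (-0.83 ± 0.17, corrected -0.36), TGM1 (-2.04 ± 0.10, corrected -1.91), KRT5 (-0.89 ± 0.08, corrected -0.77), KRT14 (-1.30 ± 0.08, corrected -1.38) and ATP2A2 (-0.55 ± 0.08, corrected -0.11) were lower (adjusted p up to 0.000199), but SPHK2 and ATP2A2 did not pass once corrected (adjusted p = 0.0729 and 0.155). SPHK1 (adjusted p = 0.0956, corrected 0.57), UGCG (0.121, corrected 0.66), S1PR1 (0.124, corrected 0.149), S1PR2 (0.575, corrected 0.696), S1PR3 (0.228, corrected 0.204), S1PR5 (0.731, corrected 0.692), STIM1 (0.42, corrected 0.00332) and ORAI1 (0.319, corrected 0.207) did not pass before the correction. SPHK1 passed without KO replicate 2 (0.00543) and S1PR3 without OE replicate 3 (0.0454). STIM1 went from -0.09 to 0.28 with the trend removed, where it passed.

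Camera called 13 lists between KO and OE cells, 9 higher and 4 lower in KO. Of 29 p53 targets 21 rose, 2 fell and 6 did not pass (21 and 2 adjusted over the list alone, 21 and 3 once corrected). GDF15 (1.77 ± 0.13, corrected 1.72) and RRM2B (1.51 ± 0.09, corrected 1.28) were higher. The list's median was 0.78, corrected 0.71 (adjusted p = 9.98e-08, corrected 2.59e-08). Of 30 matrix and transition genes 6 rose, 20 fell and 4 did not pass (6 and 20 adjusted over the list alone, 7 and 17 once corrected). FN1 (-2.30 ± 0.10, corrected -1.90) and COL4A2 (-1.84 ± 0.08, corrected -0.93) were lower, and the median was -0.98, corrected -0.73 (adjusted p = 9.22e-06, corrected 0.000144). Before the correction these were the 2 lists that passed with an estimated correlation (adjusted p = 0.023 and 0.0252), and with the trend removed both did (0.0349 and 0.0349) along with lysosomal genes (0.0349). Of 49 cell cycle genes 1 rose, 35 fell and 13 did not pass (1 and 35 adjusted over the list alone, 1 and 43 once corrected; median -0.76, adjusted p = 4.88e-10, corrected 8.59e-18, and 0.261 with an estimated correlation). YAP targets had 1 of 24 higher and 17 lower, the same over the list alone (2 and 16 once corrected), with MYOF lower (-1.12 ± 0.09, corrected -0.91; adjusted p = 0.000195, corrected 0.000362, and 0.0927 with an estimated correlation). Basal genes had 8 higher and 14 lower of 27 (9 and 14 adjusted over the list alone, 8 and 13 once corrected; adjusted p = 0.00366, corrected 0.114, and 0.226 with an estimated correlation). The genes named for these lists had adjusted p up to 2.07e-10.

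Lysosomal genes had 24 of 44 higher and 4 lower in KO than in OE cells (24 and 5 adjusted over the list alone, 28 and 2 once corrected; adjusted p = 2.39e-05, corrected 2.12e-08, and 0.086 with an estimated correlation), with LIPA, the acid lipase, higher (1.03 ± 0.08, corrected 0.88). NRF2 targets had 18 higher and 3 lower of 26, the same over the list alone (17 and 4 once corrected), with GPX2 higher (2.34 ± 0.13, corrected 1.90; adjusted p = 1.07e-06, corrected 1.08e-05, and 0.086 with an estimated correlation). All 40 ribosomal protein genes were higher, also over the list alone (median 1.26, adjusted p = 1.79e-37, corrected 3.45e-43, and 0.124 with an estimated correlation), as were 12 of 15 histones (13 over the list alone, 12 once corrected; median 2.45, adjusted p = 2.02e-08, corrected 4.94e-06, and 0.0506 with an estimated correlation). Sphingolipid genes had 21 higher and 7 lower of 44, the same over the list alone (21 and 4 once corrected), with PSAP higher (1.07 ± 0.08, corrected 1.00) and the sphingomyelinase SMPD4 lower (-1.10 ± 0.09, corrected -0.61; adjusted p = 0.02, corrected 0.0253, and 0.0927 with an estimated correlation). LIPA, GPX2, PSAP and SMPD4 had adjusted p up to 8.49e-10. S100 genes had 8 higher and 1 lower of 13 (9 and 2 adjusted over the list alone, 5 and 4 once corrected; adjusted p = 0.000306, corrected 0.114, and 0.354 with an estimated correlation). Inflammatory genes had 5 higher and 2 lower of 17, the same over the list alone (6 and 3 once corrected; adjusted p = 0.0323, corrected 0.0588, and 0.124 with an estimated correlation). Class I genes had 9 higher and 3 lower of 18, the same over the list alone (10 and 3 once corrected; adjusted p = 0.0457, corrected 0.0456, and 0.156 with an estimated correlation), a call lost without KO replicate 2 (0.0514) or OE replicate 2 (0.0624). The other 18 tested lists had adjusted p values from 0.128 to 0.998. Without a library, junction genes (OE replicate 3 left out, 0.0308) and mitochondrially encoded mRNAs (KO replicate 3 left out, 0.0214) were also called lower. With the trend removed, wound genes (corrected 0.0161) and mitochondrially encoded mRNAs (3.81e-08) were called lower too. Neither held in that fit with an estimated correlation (adjusted p = 0.11 and 0.281). Median, mean and test did not share a sign for S1P receptors, calcium, barrier, wound, fatty acid, unfolded protein response, hypoxia and fibroblast genes, of which wound genes had a median of -0.27 and a mean of 0.12.

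KO and OE calls against control overlapped in 1518 genes, of which 735 had the same sign and 783 opposite signs. The split was 532 and 937 without OE replicate 3, 796 and 721 without OE replicate 1, and 679 and 840 with the trend removed. The overlap was 999, 957 and 991 without control replicate 1, 2 or 3. Independent lists of these sizes would share 323 genes higher in both (315 found) and 324 lower in both (420 found). They would share 326 higher in KO and lower in OE (396 found) and 322 lower in KO and higher in OE (387 found). Across genes, the fold changes had a correlation of 0.0519 and a covariance of 0.0213. In 50 simulations of unchanged groups against the same controls the correlation was 0.495 and the covariance 0.0281 on average, and no gene was called in both. The 3 control libraries are too few to give each group controls of its own, so part of the overlap with the same sign may come from the shared controls.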

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

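Tests with the length and GC trend removed were chosen only after the data were seen, and the other settings before. Counts of changed genes moved little with the scaling, test or filter: KO against control gave 6951, with 6956 by DESeq2's size factors, 6840 by DESeq2, 6839 by limma-voom and 6689 without a filter, OE against control 2493, 2495, 2466, 2642 and 2413, and KO against OE 7711, 7713, 7588, 7714 and 7616. Requiring a 2-fold change left 1724, 451 and 2468 genes, by construction, and adjusted p under 0.01 left 1431 in OE against control and 724 in the overlap of 1518. Leaving out a library gave 6056 to 7201, 1729 to 2585 and 6893 to 7673 genes, 12 to 15, 11 to 16 and 12 to 14 lists, and an overlap of 957 to 1517, with 999, 957 and 991 without control replicate 1, 2 or 3. SGPL1 kept its direction and its call in all of them, at -0.70 to -0.59, 3.45 to 3.61 and -4.24 to -4.10. The estimated correlation called 0, 1 and 2 lists in place of 12, 13 and 13, and fry 20, 18 and 20. Removing the trend left 8, 13 and 12 lists, and with the title numbers as a block 7 in KO against control. The causes of these changes were not tested.

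With the trend removed STIM1 reversed to 0.28 in KO against OE and to 0.13 in KO against control, and NOTCH3 to 0.0525 (block added: 0.28, 0.12 and 0.0479). Of 455 results of named genes 422 and of 93 of lists 34 kept direction and side of the threshold in every setting fixed beforehand; removing the trend weakened 18 gene and 8 list results and strengthened 4 and 3. Title numbers are not said to pair libraries, and same-numbered libraries deviated with correlations of -0.0772 to 0.066, 0 of 9 over 0.1 (different numbers: -0.0859 to 0.109). With the number as a replicate block 6907, 2468 and 7669 genes, 12 lists each and an overlap of 1505 were called. Under this block lysosomal genes in OE (0.0553) and class I genes in KO against OE (0.0519) missed the threshold and SPHK1 passed in KO against OE (0.0457). Depth limits genes near the floor of 0.225 to 0.475 CPM. The 55.2% to 59.7% recovery of 1.5-fold changes was simulated with far fewer changed genes and no length trend, so it may differ here.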

Other observations

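Tests of depth, library preparation, the shared calls and ribosomal genes after correction, the PXDN and P3H3 neighbourhoods, separate derivation and the chromosome blocks were chosen only after the results were seen, while those of protein synthesis genes, the other neighbourhoods and the splits were set before. Markers of cell types other than keratinocytes were measured in all groups. Of 7 fibroblast markers 2 rose, 2 fell and 3 did not pass (4 and 2 adjusted over the list alone, 2 and 2 once corrected). Podoplanin PDPN rose from 2.35 ± 0.770 to 11.3 ± 1.02 CPM in KO cells (2.26 ± 0.28, corrected 2.08) and FBLN1 rose (0.32 ± 0.09, corrected 0.73), while collagen COL1A1 (25.6 ± 3.75 to 11.2 ± 3.09 CPM, -1.17 ± 0.18, corrected -0.56) and MFAP5 (-1.04 ± 0.15, corrected -1.36) fell. The list had adjusted p = 0.857 (corrected 0.673), and FBLN1 was lost without KO replicate 1 (0.054). In OE cells 0 fibroblast markers passed by edgeR over all genes or the list alone, and 0 had an unadjusted p under 0.05, with COL6A1 nearest (0.76 ± 0.45, adjusted p = 0.266; list 0.498, and 0.0417 by fry). Of 3 melanocyte markers, the trafficking protein RAB38 rose (0.91 ± 0.13, corrected 0.39) and the transcription factor MITF fell (-0.40 ± 0.09, corrected -0.38) in KO cells, the same over the list alone and once corrected (median -0.02, mean 0.16, list adjusted p = 0.857, corrected 0.846). MITF also fell in OE cells (-0.59 ± 0.09; 1 of 3 markers, and 1 higher and 1 lower over the list alone, list 0.349). Genes of these lists said to change had adjusted p up to 0.00494 in KO cells.

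Simple epithelial genes were measured as well. The keratin KRT8 went from 814 ± 76.4 to 1140.2 ± 78.3 CPM (0.49 ± 0.08, corrected 0.85) and KRT19 from 1.53 ± 1.16 to 5.77 ± 0.461 (1.91 ± 0.44, corrected 1.83; 2.71 without control replicate 1), while the mucin MUC1 fell before the correction only (-0.72 ± 0.15, corrected -0.21, corrected adjusted p = 0.236). Of 10 measured 6 rose, 3 fell and 1 did not pass (6 and 3 adjusted over the list alone, 4 and 1 once corrected) in KO cells (list adjusted p = 0.509, corrected 0.359) and 1 rose, 3 fell and 6 did not pass (1 and 3 adjusted over the list alone) in OE cells (list 0.303), where the epithelial transcription factor ELF3 fell (-0.77 ± 0.11, adjusted p = 2.22e-05). KRT8, KRT19 and MUC1 had adjusted p up to 0.00083 in KO cells. The 2 measured blood, endothelial and immune markers were too few for a list test. In KO cells 2 rose (2 over the list alone, 1 once corrected), and in OE cells 2 fell (2 over the list alone). The receptor CSF1R rose in KO (1.07 ± 0.15, corrected 1.31) and fell in OE cells (-1.07 ± 0.17), with adjusted p up to 6.46e-05. The monocyte receptor CD14 also rose in KO (0.91 ± 0.35, corrected 0.58, adjusted p = 0.0326, corrected 0.168) and fell in OE cells (-1.34 ± 0.39, 0.0186). The KO call was lost without control replicate 2 (0.155), control replicate 3 (0.0844), KO replicate 1 (0.116) or KO replicate 3 (0.106) and once corrected, and the OE call without control replicate 1 (0.129), OE replicate 1 (0.0671) or OE replicate 2 (0.0608).

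All KO libraries showed lower values for long and GC-rich genes. Depth is argued against, since the KO libraries at the depth of the controls had slopes of -0.2436 and below, and so is a rise of ribosomal, mitochondrial and translation genes, because the rank correlation with length was -0.3378 without 1165 such genes and list members. Preparation or RNA quality and the knockout itself remain open and cannot be told apart, as every KO library has the slope (libraries of a group differed by at most 0.1228). The trend is not the whole of the KO result: 4703 of 6951 calls recurred with the same sign after its removal, and the ribosomal protein median stayed at 1.0533. A part of the remaining difference may still follow RNA quality in ways that length and GC content do not capture.

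At or under 3 counts in a group were 7 genes in KO (PXDN, ARMCX1, SGCE, PEG10, TBL1X, P3H3 and NID2), 1 in OE (PXDN) and 0 in control cells, among genes named with at least 5 CPM in another group. Deletion of a large segment around PXDN is argued against by a median log2 fold change of 0.3532 over the 11 tested genes within 2000 kb, and around the other 6 by one of -0.0887 over 55 genes within 500 kb. By gene these medians were -0.1264 for P3H3 (38 genes), -0.08 for ARMCX1 (9), -0.27 for TBL1X (4) and 0.28 for NID2 (3), while PEG10 and SGCE rested on 1 shared neighbour, CASD1 (-0.09). Noticed after their values were seen were ARMCX4 next to ARMCX1 (89, 0 and 119 counts in control, KO and OE) and RPL13P5 near P3H3 (50, 9 and 26). A smaller deletion, or one away from the measured neighbours, stays open for all 7. Separate derivation of the cell lines is a candidate explanation for all 7, as is an effect of the edit, and cell line and genotype are the same split here.

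Neighbouring genes were higher together in KO cells on chromosome 1 from 173.4 to 248.9 Mb (313 genes, 164 higher and 27 lower) and chromosome 5 from 0.2 to 54.3 Mb (120 genes, 63 and 13), both with a corrected median of 0.41. OE cells had 0.12 and -0.01 there, and on chromosome 1 they too exceeded the shuffles, with a highest mean over 4 windows of 0.1777 against 0.1372 and a run of 3 windows against at most 2. The regions, the windows of 30 genes and the threshold of 0.15 were chosen after looking at the window medians, chromosome 5 was taken over equal runs on chromosomes 12 and 15, and its run of 4 windows was no longer than the longest shuffled run. The length and GC trend is argued against as the whole cause for the stretches of 4 windows that were highest before correction, chromosome 1 from 220 to 246.8 Mb and the chromosome 5 region, which kept medians of 0.4995 (95% interval 0.3864 to 0.6377) and 0.4081 (0.2515 to 0.5104). The next, on chromosome 8, went from 0.3676 to 0.1454. The rest of the chromosome 1 region was chosen on corrected values, so its corrected median tests nothing. The order of genes by chance is argued against too, with a run of 11 windows on chromosome 1 against at most 6 in 200 shuffles, and a highest mean over 4 windows on chromosome 5 of 0.3686 against 0.2666. A gain of these segments in the KO cells may be a hypothesis, but the lowest median over KO libraries and 3 classes of genes by expression, 0.1497, lay between the bounds of 0.1 and 0.2 set for it, so the test did not decide, nor had it when first run with chromosome 12 in place of chromosome 5. Copy number was not analysed here.

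Each comparison of 3 with 3 libraries allows 10 splits, too few for a share under 0.05. The real split gave 6951, 2493 and 7711 genes and was the only 1 of the 10 to give as many, with the highest other at 0 in each case by edgeR (at most 329, 751 and 446 genes at an unadjusted p under 0.05). For lists the real split gave 12, 13 and 13, again 1 of 10, with the highest other at 6, 8 and 12 (11, 14 and 16 unadjusted).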
